A study of Mus musculus with 12 samples.

How the data were processed

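The deposited values were counts: per the labels, the authors made libraries with the 10x Chromium 3′ version 2 chemistry, so each count is a unique molecular identifier (UMI) near the 3′ end of a transcript. The submitters' processing notes name Cell Ranger 2.0.2 and the mm10 build, without stating what each step did. The deposited matrix held 18601 genes by 32763 cells with whole-number values, and a cell table gave the library, genotype, tissue and batch of every cell. How the authors filtered cells and genes is not given in the sources used here, and no cell was removed for the main results. The lowest count of UMIs in a kept cell was 474 to 1746 depending on the library, and the genes per cell ran from 41 to 7170. Of all cells, 358 (1.09%) had over 10% mitochondrial UMIs. No doublet caller was run, because the loading of each channel is not given in the sources used here. The genotype and tissue columns of the cell table, 2 columns in all, were not used, because the library names and the labels carry the same facts. The symbols of 20 genes were repeated in the matrix and were told apart by their identifiers.

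Groups came from the labels: genotype of the transferred Th1 cells and tissue. The labels number the samples as replicates and do not say whether each came from a separate animal. The p-values of single genes and of cluster shares therefore measure the spread between samples. The batch column equalled the replicate number for all 32763 cells. Batch 1 held 4 libraries (spleen and colon lamina propria) and batch 2 held 8 libraries, with small intestine and colon epithelium only in batch 2. Samples with the same number deviated together from their group means (pairwise correlations 0.31 to 0.61, and 0.27 to 0.59 without sex-linked genes), so the numbers were read as pairing the samples. The main fits were also made with the replicate number as a block. In the model over all 12 libraries the block was each pair of tissue and replicate number, in place of the tissue term.

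UMIs were summed per gene and library over all cells. The contrasts, the 31 gene lists and the alternatives were fixed before the data were examined, apart from the rule for CD3-low clusters, the CD3-high fit with a block, the mitochondrial limit and the single-batch fits, which were set after results were seen. Genes were kept with filterByExpr, libraries scaled by TMM (factors 0.842 to 1.12), and groups compared with the quasi-likelihood test of edgeR with robust dispersions, with Benjamini-Hochberg adjustment at 0.05. Standard errors were derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. The 4 groups with 2 libraries each were fitted together (11636 genes). A further model over all 12 libraries tested the genotype across 6 pairs with tissue as a further term (12044 genes). Lists were tested with camera at its preset correlation of 0.01, with the result at an estimated correlation beside it, and a list needed 3 tested genes. Camera sets the genes of a list against all other genes, and the preset takes them as nearly independent. Its p-values at the preset therefore measure spread across genes rather than between samples. Lists for CD8 T cells, gamma delta T cells and plasma cells had fewer and were not tested. List members were also adjusted over the list alone. Small intestine and colon epithelium have 1 library per group, so no test was run there. CPM values carry exact Poisson 95% intervals, ratios carry exact conditional 95% intervals, and both cover counting error only. Median log2 ratios of lists there took members with at least 5 CPM on average, with 1 CPM added, and were ranked among 10000 random lists matched in size and level, as a description of these libraries.

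Cells were clustered with scanpy (counts scaled to 10000 per cell, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.6, seed 1), giving 17 clusters. The rule called 6 clusters CD3-low, where the mean log2 difference of T cell markers from all other cells was -1 or lower. These clusters held 1755 cells (5.36%). Every fit was repeated without them, and those values are marked as coming from the CD3-high clusters. Clusters were described by their leading genes. Shares of clusters with at least 50 cells were compared by edgeR on cell counts per library, with exact binomial 95% intervals per library.

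Genes named in the text follow a fixed rule. It takes 18 genes always, and in each tested comparison the 10 largest fold changes each way among genes past the threshold with mean CPM of at least 10 and every library on the same side. Where none passed it takes the 5 smallest p-values each way, said not to pass. It adds up to 4 members per list by p-value and, without replicates, the 5 largest CPM ratios each way among genes with at least 50 UMIs in each library. Some genes that the rule takes are not reported here. Predicted genes, Rik clones and receptor segments were counted but not named. Exceptions are genes called only under an alternative, leading genes of clusters and the markers in the closing part. Identifiers came from the deposited gene table and positions from GENCODE vM21 on mm10.

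Alternatives were a block for the replicate number, DESeq2, DESeq2 size factors within edgeR, limma on the log2 mean per cell of values scaled to 10000 (0.01 added), no expression filter, libraries thinned to equal depth, CD3-high clusters only with and without a block, proliferating cells left out, the libraries of a single tissue or of the 2 replicated tissues alone, cells over 10% mitochondrial UMIs left out, Leiden resolutions of 0.3 and 1, each batch alone and each library left out in turn. Fits that left a library out had no block. Leaving out a spleen or colon lamina propria library set a group from a single batch against a group from both. Those shifts may therefore reflect batch as well as the library. The pipeline was tested on simulated data made from the same libraries, with 100 genes changed 2-fold and 100 changed 4-fold. Simulated libraries were drawn independently, so they held no deviation shared within a batch. Of the 2-fold changes edgeR recovered 2% in colon lamina propria between genotypes, 6% in spleen, 1% for the interaction, 2% and 6% between tissues in control and KO, and 63% across all tissues, from 11636 or 12044 genes simulated. Of the 4-fold changes it recovered 54%, 55%, 15%, 50%, 56% and 80% in the same order. False calls numbered 5, 5, 3, 5, 6 and 6, and no recovered gene had the wrong sign. DESeq2 gave 20, 39, 28, 34, 30 and 18 false calls in the same order.

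Versions were Python 3.11.15, scanpy 1.11.5, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.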

Results

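Single-cell 3′ profiles of CD4 T cells were collected from recipients of Th1 cells that kept (control) or lacked (KO) the interleukin-23 receptor. Spleen and colon lamina propria had 2 libraries per genotype, and small intestinal lamina propria and colon epithelium had 1 library per genotype. The 12 libraries held 32763 cells (16288 control, 16475 KO) and 112503395 UMIs, with 3107528 to 14292028 UMIs and 981 to 4079 cells each. Median depth was 1863 to 5711 UMIs per cell by library, and 2807 UMIs and 1218 genes over all cells. Over the 8 spleen and colon lamina propria libraries, the first principal component of the summed counts parted tissues (58.8% of variance) and the second parted the batches (21.0%). Batch 1 libraries measured 774 to 1034 CPM of Xist, the RNA that silences an X chromosome, and batch 2 libraries 0 to 0.31 CPM. Genes of the Y chromosome ran the other way, with Eif2s3y at 51.8 to 115 CPM in batch 2 and 0 in batch 1.

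Il23r (ENSMUSG00000049093, chr6:67422932-67491855) encodes the receptor subunit altered in the KO cells. It measured 8.48 and 1.31 CPM in the spleen control libraries, 16 and 1.76 CPM in spleen KO, 3.60 and 1.97 CPM in colon lamina propria control, and 5.46 and 3.79 CPM in colon lamina propria KO (batch 1, then batch 2). Small intestinal control and KO measured 3.41 and 34.1 CPM, and colon epithelium 0.60 and 0.298 CPM. The tags count transcripts near their 3′ end, so these values check no label. With 6 clusters of low CD3 expression left out, Il23r measured 1.13 and 0.949 CPM in spleen control, 1.82 and 0.454 in spleen KO, 0.996 and 1.66 in colon control, and 2.48 and 2.08 in colon KO. The small intestinal values were then 3.47 and 4.61 CPM, and the epithelial values 0.602 and 0.321 CPM. The CD3-low clusters held 18.8% and 1.72% of spleen control cells, 22.0% and 3.29% of spleen KO, 5.93% and 1.16% of colon control, 7.33% and 2.70% of colon KO, 1.07% and 29.1% of small intestinal control and KO, and 0.270% and 3.88% of epithelial control and KO.

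The comparison of KO with control in colon lamina propria asked whether T cells in the gut differ when the transferred cells lack the receptor. No single gene passed there. Il17a (ENSMUSG00000025929, chr1:20730905-20734496), a cytokine of Th17 cells, measured 15.9 ± 1.85 CPM in control and 40.7 ± 10.9 CPM in KO (mean ± SD, n = 2; log2 fold change 1.39 ± 0.84, SE). Il10, an anti-inflammatory cytokine, measured 4.40 ± 2.46 and 10.0 ± 0.81 CPM (1.19 ± 0.79). Ifng (ENSMUSG00000055170, chr10:118441046-118445892), the defining Th1 cytokine, measured 256 ± 62.9 and 274 ± 86.7 CPM (0.09 ± 0.40), and Tbx21, the Th1 transcription factor, gave 0.29 ± 0.37. Gzma (ENSMUSG00000023132, chr13:113093825-113100981), a granule protease, measured 1168 ± 847 and 620 ± 8.48 CPM (-0.83 ± 0.68). Its pair ratio was 0.14 in batch 1 and -1.52 in batch 2, and without control 2 Gzma gave 0.05. Il22 (ENSMUSG00000074695, chr10:118204942-118210047), a cytokine that acts on epithelium, measured 427 ± 445 and 1194 ± 873 CPM (1.47 ± 1.46), and 0.62 in the CD3-high clusters. The adjusted p of each of these genes was 1.

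The smallest p-values in colon lamina propria, none of which passed (adjusted p = 1), belonged on the higher side to Platr17 (1.31 ± 0.32), Cox4i2 (0.04 and 1.43 CPM), the phosphatase gene Dusp14 (25.3 and 49.9 CPM), the Aiolos gene Ikzf3 (0.66 ± 0.21) and Taf7 (0.50 ± 0.16). On the lower side they belonged to Apoe (-1.49 ± 0.34), a lipid carrier made by macrophages, Tpsb2 (2.07 and 0 CPM), Fry (-1.14 ± 0.31), Tha1 (-1.45 ± 0.39) and Klra3 (-2.74 ± 0.77). Apoe gave -0.26 in the CD3-high clusters. By edgeR 0 of 11636 genes passed, with 103 at an unadjusted p under 0.05, and DESeq2 and limma also called 0. With the replicate number as a block 1 gene passed, the antimicrobial lectin gene Reg3b (lower in KO, adjusted p = 0.0459), which was singled out after its values were seen.

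Among fixed lists in colon lamina propria, 7 passed by camera. The list of dissociation and heat shock genes rose in KO, with all 24 measured members on the higher side (median 0.51, adjusted p = 2.0e-10, and 0.685 with an estimated correlation). Dnajb1, a cochaperone, gave 1.90 ± 0.93, Hsph1 1.25 ± 0.87 and Hspa8 0.55 ± 0.38. The Th17 list rose with 14 of 19 members higher (median 0.29, adjusted p = 0.00855, and 0.685 with an estimated correlation), led by Ccl20, a chemokine for CCR6-bearing cells (0.98 ± 0.53). The co-inhibitory receptor list rose with 9 of 14 members higher (0.32, adjusted p = 0.00222, and 0.685 with an estimated correlation), among them Pdcd1 (0.82 ± 0.31) and Lag3 (1.08 ± 0.57), which encode checkpoint receptors. The naive and central memory list fell, with 4 of 18 members higher (-0.32, adjusted p = 0.00222, and 0.685 with an estimated correlation), among them Klf2 (-0.67 ± 0.29) and S1pr1 (-0.59 ± 0.28), genes of lymphocyte egress, and Tcf7 (-0.32 ± 0.18). In each of these lists 0 members passed over all genes or adjusted over the list alone. Pair medians in batch 1 and batch 2 were 0.03 and 1.17 for heat shock, 0.48 and 0.43 for Th17, 0.20 and 0.20 for co-inhibitory receptors, and 0.04 and -0.52 for naive genes. Lists of Th1 genes (median 0.15, adjusted p = 0.0609), cytotoxic genes (0.05, 0.808) and TCR activation genes (0.18, adjusted p = 0.0638, and 0.0467 with the block) did not pass.

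Which libraries were included changed each of these colon list results. Fits that left a library out had no block, so they also unbalanced the batches between genotypes. Heat shock genes gave 0.11 without control 2 (adjusted p = 0.236) and 1.23 without control 1. Th17 genes gave 0.07 without KO 1 (adjusted p = 0.405), 0.29 without control 2 (0.895), 0.45 without KO 2 (0.0914) and 0.44 without control 1, and the call also ended without the expression filter (0.0988). Co-inhibitory receptor genes gave 0.17 without KO 1 (0.0947), 0.06 without control 2 (0.332) and 0.50 without control 1, and 0.33 in the CD3-high clusters (0.0505). Naive genes gave -0.23 without control 2 (0.0964), -0.06 without KO 2 (0.892), -0.58 without KO 1 and -0.20 in the CD3-high clusters (0.0635). Over 18 alternatives the adjusted p ran from 1.0e-15 to 0.685 for heat shock, 1.6e-05 to 0.895 for Th17, 0.00113 to 0.685 for co-inhibitory receptors and 1.2e-07 to 0.892 for naive genes.

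Markers of other cell types moved beside these T cell lists in colon lamina propria. Macrophage markers fell in KO (1 of 12 higher, median -1.56, adjusted p = 6.0e-05), as did epithelial markers (2 of 14 higher, -1.47, adjusted p = 2.2e-06) and stromal markers (-0.84, adjusted p = 0.0164). With an estimated correlation each had adjusted p = 0.685. In the CD3-high clusters the medians were -0.06 (adjusted p = 0.985), 0.16 (0.866) and 0.44 (0.111). C1qb, a complement gene of macrophages, gave -2.30 ± 0.91 in all cells and -0.20 in the CD3-high clusters, and Lyz2, a myeloid lysozyme, -1.86 ± 1.04 and -0.45. The macrophage call ended without control 1 (0.25, adjusted p = 0.684), and the median was -2.52 without control 2. The epithelial call ended without KO 1 (-0.47, 0.508) or control 2 (0.58, 0.995), and the median was -2.30 without control 1 and -5.16 without KO 2. The stromal call ended without control 1 (-0.18, 0.668), control 2 (-0.86, 0.0733) or KO 2 (-0.17, 0.839), and the median was -1.34 without KO 1. Over 18 alternatives the adjusted p ran from 4.2e-16 to 0.985 for macrophage, 2.3e-17 to 0.995 for epithelial and 1.8e-05 to 0.970 for stromal markers.

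**Figure D1:**
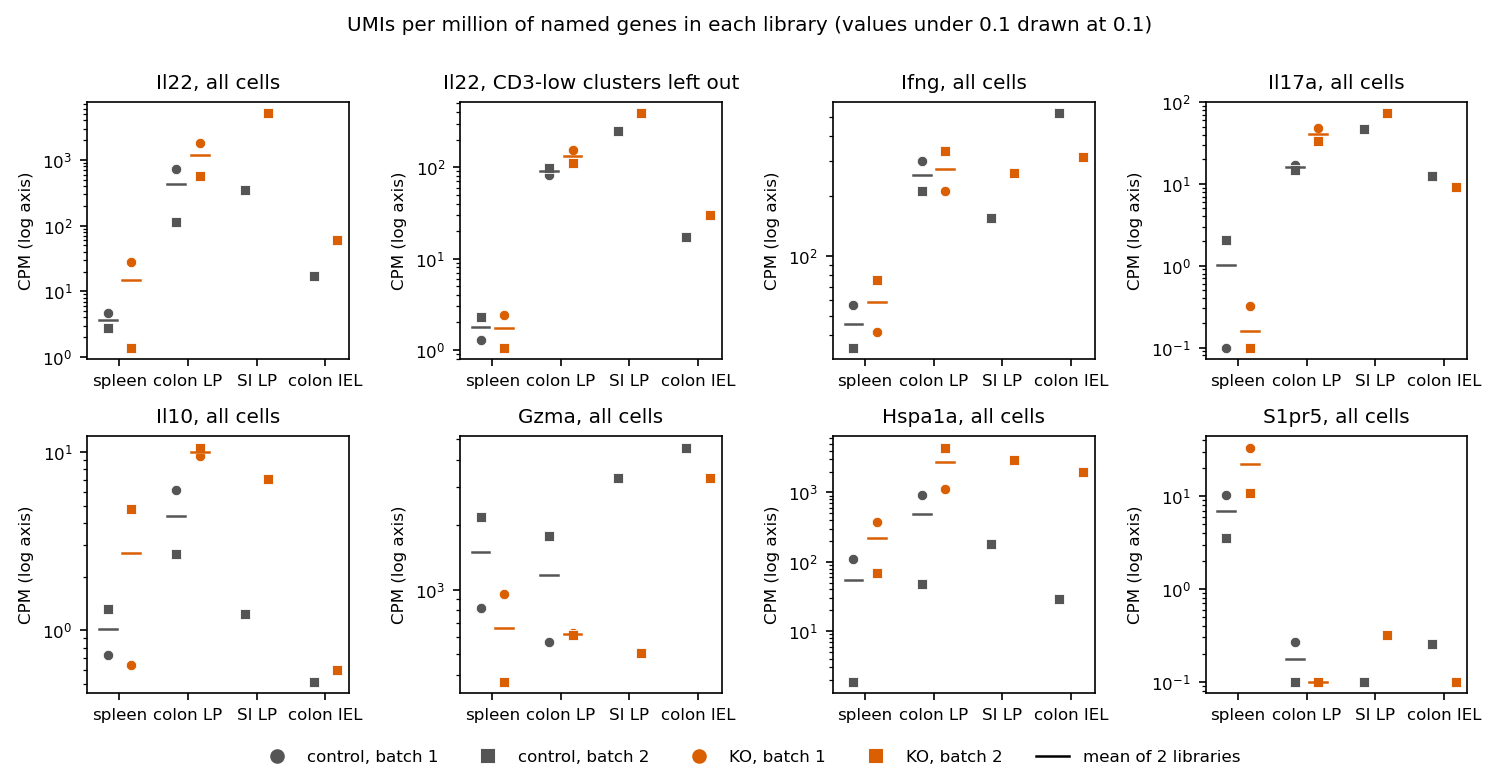
CPM of 7 named genes in every library on a log axis, with Il22 shown for all cells and with CD3-low clusters left out. Circles are batch 1, squares batch 2, grey control and orange KO, lines are means of 2 libraries, and values under 0.1 CPM are drawn at 0.1.

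The same comparison in spleen asked whether the receptor mattered outside the gut. Il7r, the interleukin-7 receptor gene, measured 397 ± 110 CPM in control and 240 ± 91.8 CPM in KO (-0.76 ± 0.31), Gzma 1494 ± 950 and 661 ± 408 CPM (-1.21 ± 0.69), Ifng gave 0.33 ± 0.40 and Tcf7 0.01, each with adjusted p = 1. Pair ratios in batch 1 and batch 2 were 0.21 and -2.54 for Gzma and -0.07 and -1.43 for Il7r. The smallest p-values on the higher side belonged to genes of basophils and mast cells. Prss34 (ENSMUSG00000056399, chr17:25298394-25300165), a basophil protease, measured 0 CPM in control and 30.8 ± 16.9 CPM in KO, Mcpt8, another, 0.30 ± 0.43 and 38.1 ± 11.1 CPM (7.03 ± 1.02), and the transcription factor gene Gata2 gave 5.37 ± 1.12, with Cd63 (3.78 ± 0.77), a granule membrane protein, and Tnfaip2 (0 and 0.85 CPM) beside them. On the lower side were Apoe (-1.52 ± 0.35), the NK receptor gene Klrb1c (-1.54 ± 0.40), Mir142hg, Fxyd1 (0.26 and 0 CPM) and Atp8a2. None passed by edgeR (0 genes, 120 at an unadjusted p under 0.05). DESeq2 called 2 genes (Cd63 and Prss34), limma 2 (Mcpt8 and Prss34), and edgeR with a block 1 (Prss34, adjusted p = 0.0323, against 3.3e-07 to 1 over 17 alternatives), all higher in KO. In the CD3-high clusters Prss34 measured 0 CPM in control and 0.807 and 0.530 CPM in KO, Mcpt8 0 CPM and 1.21 and 0.757 CPM, and with a block no gene passed there (smallest adjusted p = 0.292). Without spleen KO 2, edgeR called Cd63 (adjusted p = 0.0274, against 0.000192 to 1 over 19 alternatives).

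In spleen 11 lists passed by camera. Interferon-stimulated genes rose in KO, with 29 of 30 higher (median 0.48, adjusted p = 2.5e-15, and 0.372 with an estimated correlation). Among them Ifi27l2a measured 494 ± 297 and 1093 ± 23.3 CPM (1.11 ± 0.53), and the GTPase genes Iigp1 (0.88 ± 0.45) and Gbp4 (0.46 ± 0.22) lay on the same side. Ribosomal protein genes fell, with 0 of 37 higher (-0.32, adjusted p = 1.1e-10, and 0.657 with an estimated correlation), Rps18 at -0.40 ± 0.23. Naive and central memory genes fell, with 4 of 18 higher (-0.32, adjusted p = 6.2e-05, and 0.372 with an estimated correlation), among them Igfbp4 (-1.61 ± 0.61) and the survival gene Bcl2 (-0.60 ± 0.34). Co-inhibitory receptor genes rose, with 11 of 14 higher (0.42, adjusted p = 0.000248, and 0.30 with an estimated correlation), among them Tox2 (0.69 ± 0.26) and Tox (0.96 ± 0.38), regulators of exhaustion. Proliferation genes rose, with 32 of 32 higher (0.39, adjusted p = 0.00782, and 0.834 with an estimated correlation), Hmgb2 at 0.40 ± 0.27. No member of these lists passed over all genes or adjusted over the list alone.

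These spleen lists differed between the batches. Pair medians in batch 1 and batch 2 were 0.08 and 0.84 for interferon-stimulated genes, -0.14 and -0.42 for ribosomal genes, -0.05 and -0.41 for naive genes, 0.29 and 0.57 for co-inhibitory receptors, and -0.43 and 0.92 for proliferation genes. Interferon-stimulated genes gave 0.96 without control 1 and 0.20 without control 2, naive genes -0.15 without KO 2, and co-inhibitory receptor genes 0.17 without control 2, each still past the threshold. Proliferation genes turned to -0.43 without KO 2 (adjusted p = 0.00032), gave 0.34 without control 2 (0.207) and 0.85 without KO 1. Over 18 alternatives the adjusted p ran from 9.2e-20 to 0.372 for interferon-stimulated, 1.9e-13 to 0.657 for ribosomal, 2.8e-06 to 0.372 for naive, 1.1e-05 to 0.30 for co-inhibitory and 3.9e-16 to 0.834 for proliferation genes.

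Lists of other cell types rose in spleen KO as well. Mast cell and basophil markers had 3 of 4 members higher (median 5.88, and 1.46 without KO 1; adjusted p = 6.9e-20, and 0.105 with an estimated correlation), and 3 members passed when adjusted over the list alone. Over 16 alternatives the adjusted p ran from 2.0e-25 to 0.105, and in the CD3-high clusters too few members were kept for a test. Erythroid markers had 5 of 5 higher (median 2.81, 10.21 without control 1 and 8.77 with a block; adjusted p = 7.0e-05, and 0.601 with an estimated correlation), with the haemoglobin gene Hbb-bs at 225 ± 318 and 1620 ± 1108 CPM. Without KO 2 the erythroid call ended (2.07, adjusted p = 0.0628). NK and ILC markers had 8 of 8 higher (median 0.65; adjusted p = 0.0267, and 0.601 with an estimated correlation), and the call ended without KO 1, where the median turned to -0.14 (0.891), without control 2 (0.24, 0.329), without the filter (0.388) and at equal depth (0.336). The median was 1.85 without control 1 and 1.27 without KO 2. Neutrophil markers (median 1.60, adjusted p = 0.0149, and 0.601 with an estimated correlation), Th1 genes (0.13, 0.0375, 0.657 and, with a block, 0.0785) and dendritic cell markers (0.52, 0.0438 and 0.834) also passed on the higher side. The neutrophil call ended without spleen control 1 (0.61, 0.868) or KO 2, where the median turned to -0.98 (0.316), in the CD3-high clusters (1.21, 0.101), without the filter (0.0768) and at equal depth (0.122), and the median was 10.71 without control 2. The Th1 call ended without spleen control 1 (0.20, 0.186), control 2 (0.323) or KO 2 (0.316) and without colon control 1 (0.0878) or control 2 (0.0690), and the dendritic call without spleen KO 1 or control 2, where the median turned to -1.30 (0.342) and -0.37 (0.118), and without colon KO 1 (0.0708), control 2 (0.0527) or KO 2 (0.101), and its median was 3.10 without spleen control 1 and 1.28 without KO 2. The dendritic call also ended without the filter (0.116), at equal depth (0.657), with DESeq2 size factors (0.0586) and in a fit of spleen alone (0.274). Over 18 alternatives the adjusted p ran from 8.4e-09 to 0.601 for erythroid, 0.00294 to 0.891 for NK and ILC, 7.5e-13 to 0.868 for neutrophil, 0.0177 to 0.657 for Th1 and 4.3e-07 to 0.834 for dendritic genes. T cell markers themselves gave a median of -0.01 (adjusted p = 0.994).

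The interaction asked whether the KO effect differed between colon lamina propria and spleen. Il17a gave 4.66 ± 1.92 and Ifng -0.25 ± 0.57 (log2 colon effect minus spleen effect), both with adjusted p = 1. The size of the Il17a value rests on very low spleen counts. Spleen control and KO measured 0 and 0.319 CPM in batch 1, and 2.06 and 0 CPM in batch 2. The smallest p-values belonged to Platr17 (1.85 ± 0.45), the insulin signalling gene Irs2 (2.26 ± 0.64), Mir142hg (1.43), Ly6k (3.74) and the oxygen sensor gene Egln3 (1.19) on the higher side, and to Tnfaip2, Tgfbi (-2.92 ± 0.70), Gata2, Aqp1 and Klf1 on the lower side. By edgeR 0 genes passed (92 at an unadjusted p under 0.05), and 0 by DESeq2 and by limma. Among lists 7 passed. Proliferation genes (1 of 32 higher, median -0.69, adjusted p = 0.00223) and interferon-stimulated genes (2 of 30 higher, -0.42, adjusted p = 6.6e-06) gave a lower effect in colon. Heat shock genes (19 of 24 higher, 0.27, adjusted p = 0.00220) and ribosomal genes (37 of 37 higher, 0.26, adjusted p = 0.00153) gave a higher effect in colon. Each had adjusted p = 0.928 with an estimated correlation, and no member passed over all genes or adjusted over the list alone. The call for proliferation genes ended without colon KO 1 (-0.31, adjusted p = 0.817), spleen control 2 (0.0761) or spleen KO 2 (0.23, 0.0982), and the direction turned without colon control 2 (0.35, adjusted p = 0.0072). The interferon call ended without colon control 1 (-0.18, 0.597) or spleen control 2 (-0.22, 0.443).

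The calls for heat shock and ribosomal genes also changed when single libraries were left out, though not with all the same ones. The heat shock interaction ended without spleen control 1 (0.06, adjusted p = 0.624), spleen KO 2 (-0.12, 0.996), colon control 2 (-0.14, 0.991) or colon KO 2 (0.17, 0.191). The ribosomal interaction ended without colon KO 1 (-0.08, 0.845), spleen KO 2 (0.18, 0.112) or colon control 2 (0.12, 0.395). Where a call was kept, proliferation genes gave -1.22 without spleen KO 1, -1.35 without colon control 1 and -1.10 without colon KO 2, and interferon-stimulated genes -0.89 without spleen control 1 and -0.68 without colon control 2. Heat shock genes then gave 0.92 without spleen KO 1, 0.91 without colon control 1, 0.41 without colon KO 1 and 0.68 without spleen control 2, and ribosomal genes 0.41 without colon control 1 and 0.52 without colon KO 2. Over 17 alternatives the adjusted p ran from 1.4e-15 to 0.928 for proliferation, 6.5e-13 to 0.928 for interferon-stimulated, 3.3e-12 to 0.996 for heat shock and 6.1e-11 to 0.928 for ribosomal genes.

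The comparison of colon lamina propria with spleen in control recipients asked how the transferred cells differ by site. Any effect of tissue preparation goes with tissue, here and in KO recipients, so it cannot be told apart from a difference by site. Ifng rose from 45.5 ± 15.4 CPM in spleen to 256 ± 62.9 CPM in colon (log2 fold change 2.72 ± 0.43, adjusted p = 0.0170), and the granzyme gene Gzmb (ENSMUSG00000015437, chr14:56258838-56262260) from 234 ± 52.2 to 701 ± 264 CPM (1.76 ± 0.31, adjusted p = 0.0213). Areg (ENSMUSG00000029378, chr5:91139599-91148432), a growth factor of tissue repair, rose from 0.43 ± 0.44 to 91.3 ± 2.57 CPM (7.78 ± 0.55, adjusted p = 0.00198). The orphan receptor gene Nr4a2 (ENSMUSG00000026826, chr2:57106830-57124003), induced by antigen receptor signalling, rose by 6.53 ± 0.52 (adjusted p = 0.00302), and Nr4a1 by 5.48 ± 0.68 (adjusted p = 0.0101). Ctla4 (ENSMUSG00000026011, chr1:60887000-60915832), an inhibitory receptor, rose from 15.2 ± 3.97 to 519 ± 156 CPM (5.33 ± 0.38, adjusted p = 0.00174), and Tnfaip3, an inhibitor of NF-kappa B, from 14.8 ± 0.90 to 482 ± 55.5 CPM (5.24 ± 0.31, adjusted p = 0.00166). Also among the largest rises was Dusp4, a phosphatase gene induced by activation (5.39 ± 0.47, adjusted p = 0.00348).

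Other genes fell from spleen to colon in control recipients. Ly6c2 (ENSMUSG00000022584, chr15:75108158-75111970), a surface antigen of effector cells in blood, fell from 489 ± 290 to 43.9 ± 25.9 CPM (-3.31 ± 0.61, adjusted p = 0.0308). Itgb1 (ENSMUSG00000025809, chr8:128685654-128733200), the beta 1 integrin, fell from 588 ± 280 to 75.4 ± 10.5 CPM (-2.74 ± 0.36, adjusted p = 0.00911), and the tetraspanin gene Tspan32 (ENSMUSG00000000244, chr7:143005046-143019644) from 182 ± 2.19 to 21.5 ± 5.67 CPM (adjusted p = 0.00244). The granzyme gene Gzmm, the Notch regulator gene Dtx1 and Nsg2 fell by 2.34, 2.48 and 3.04. Il17a measured 1.03 ± 1.46 and 15.9 ± 1.85 CPM (4.05 ± 1.03, adjusted p = 0.0766, and 0.0402 with a block, within 0.00337 to 0.291 over the alternatives). Il22 measured 3.71 ± 1.27 and 427 ± 445 CPM (7.15 ± 1.90, adjusted p = 0.0898, and 0.0142 with a block, within 0.000100 to 0.373). Tbx21 gave -0.25, Gzma -0.20 and Tcf7 -0.03, none past the threshold.

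In control recipients edgeR called 669 genes between the tissues, 504 higher and 165 lower in colon, and 1717 genes (1118 higher, 599 lower) with the replicate number as a block. Of the calls 75.3% were higher, against 65.1% with the block and 54.6% by limma, whose scaling put the median gene at -0.22 here and -0.29 in KO against -0.01 and -0.04 by edgeR. Changes are therefore relative to the median gene of each scaling. Single libraries moved the count strongly: 10 genes without spleen control 1, 17 without spleen control 2, 264 without colon control 1, 421 without colon KO 1 and 425 without colon KO 2. Areg, Tspan32, Ctla4 and Tnfaip3 passed without any single library. Without spleen control 1 and without spleen control 2 the calls ended for Nr4a2 (0.0576 and 0.0532), Nr4a1 (0.0956 and 0.0930), Ifng (0.0906 and 0.115), Gzmb (0.169 and 0.0966), Dusp4 (0.0591 and 0.0656), Gzmm (0.0876 and 0.0811), Dtx1 (0.0588 and 0.0677) and Nsg2 (0.0669 and 0.0579). The Ly6c2 call ended without spleen control 1 (0.122), spleen control 2 (0.0677), spleen KO 1 (0.0622), spleen KO 2 (0.0622), colon control 1 (0.17) or colon control 2 (0.0548), and without the filter (0.0950). Ifng also ended without colon control 1 (0.0581), and Itgb1 ended without spleen control 1 (0.0580).

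Lists of T cell activation and residency rose from spleen to colon in control recipients, as did the list of dissociation and heat shock genes. TCR activation genes had 17 of 19 on the higher side, and 10 passed, all higher (11 adjusted over the list alone; camera adjusted p = 3.1e-15, and 0.124 with an estimated correlation), among them Irf4 (3.24 ± 0.27) and the NF-kappa B gene Rel (3.15 ± 0.26). STAT3 target genes had 8 higher and 1 lower of 18 (9 and 1 over the list alone; median 1.72, adjusted p = 1.6e-09, and 0.0982 with an estimated correlation), among them Bhlhe40 (2.87 ± 0.29), Hif1a (2.72 ± 0.26) and Pim1 (2.68 ± 0.28) higher and Il6ra (-2.76 ± 0.34) lower. Tissue residency genes had 8 higher and 2 lower of 22 (15 and 2 over the list alone; median 1.36, adjusted p = 5.5e-09, and 0.136 with an estimated correlation), with Rgs1 rising from 78.6 ± 15.5 to 1479 ± 493 CPM. Heat shock genes had 5 higher of 24 (7 over the list alone; median 1.66, and 0.49 without colon control 1, adjusted p = 3.0e-08, and 0.371 with an estimated correlation), all 24 on the higher side. Th17 genes had 4 higher of 19 (9 over the list alone; median 1.64, adjusted p = 6.2e-06, and 0.309 with an estimated correlation), including Rora (2.14 ± 0.24), and Th1 genes 5 higher and 1 lower of 20 (7 and 2 over the list alone; adjusted p = 0.00444, and 0.371 with an estimated correlation). The estimated correlation gave the highest adjusted p of 17 alternatives for each of these lists, and the lowest were 4.0e-20, 1.4e-11, 8.3e-12, 6.9e-11, 3.2e-11 and 0.000320 in the order given. Without spleen control 1 and without spleen control 2 the calls ended for Irf4 (0.0514 and 0.0509), Rel (0.0530 and 0.0509), Bhlhe40 (0.0604 and 0.0677), Hif1a (0.0618 and 0.0677), Pim1 (0.0794 and 0.0677), Il6ra (0.0810 and 0.0677) and Rora (0.0872 and 0.0747), and the Rgs1 call ended without spleen control 1 (0.0514).

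Further lists, 13 in all, passed between the tissues in control recipients. Apoptosis and survival genes had 11 higher of 22 (14 and 3 lower over the list alone; adjusted p = 1.0e-09, and 0.141 with an estimated correlation), and Treg genes 4 higher of 13 (5 and 1 lower over the list alone; adjusted p = 1.2e-05, and 0.142 with an estimated correlation). Naive and central memory genes had 0 higher and 3 lower of 18 (1 and 9 over the list alone; adjusted p = 0.000129, and 0.235 with an estimated correlation). Proliferation genes fell as a list with 1 of 32 higher and no member past the threshold (median -0.70, adjusted p = 0.000789, and 0.828 with an estimated correlation). Co-inhibitory receptor genes passed as higher (adjusted p = 0.0305, and 0.309 with an estimated correlation) although their median was -0.01, and 3 of 14 members rose (3 over the list alone). The co-inhibitory call ended without spleen KO 1 (0.0531), spleen control 2 (0.114), spleen KO 2 (0.0506) or colon KO 2 (0.0789), and without the filter (0.195). Without colon control 1 the Th1 call (0.0520) and the proliferation call (-0.14, 0.316) ended, and without colon control 2 the proliferation median was -1.87. With proliferating cells left out the proliferation genes gave -0.20 (0.195). Stromal markers rose with the colon libraries (7 of 11 higher, 8 over the list alone; adjusted p = 5.0e-17, and 0.124 with an estimated correlation), Sparc at 0 CPM in spleen and 28.1 ± 10.5 CPM in colon (its call ended without spleen control 1, 0.0906, spleen control 2, 0.0845, or colon control 1, 0.0529). Epithelial markers had 1 higher of 14 (5 over the list alone; adjusted p = 1.6e-06, 0.382 with an estimated correlation, and 0.115 in the CD3-high clusters). Over 17 alternatives the adjusted p ran from 9.2e-12 to 0.141 for apoptosis, 6.1e-07 to 0.142 for Treg, 3.1e-06 to 0.235 for naive, 9.6e-10 to 0.828 for proliferation, 0.00300 to 0.309 for co-inhibitory, 1.2e-19 to 0.124 for stromal and 2.8e-14 to 0.382 for epithelial genes.

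The tissue comparison in KO recipients asked whether the same site differences arise without the receptor. Areg rose from 0.41 ± 0.35 to 109 ± 8.25 CPM (8.05 ± 0.56, adjusted p = 0.00160), Ctla4 by 5.80 ± 0.39 (adjusted p = 0.00124), Nr4a2 by 5.93 ± 0.49 (adjusted p = 0.00291), Ifng from 58.4 ± 24.4 to 274 ± 86.7 CPM (2.48 ± 0.42, adjusted p = 0.0183) and Gzmb from 195 ± 61.0 to 707 ± 142 CPM (2.12 ± 0.32, adjusted p = 0.0103). Il17a rose from 0.16 ± 0.23 to 40.7 ± 10.9 CPM (adjusted p = 0.0205). S1pr5 (ENSMUSG00000045087, chr9:21242912-21248443), an egress receptor of cytotoxic cells, fell from 22.2 ± 16.1 to 0.03 ± 0.05 CPM (adjusted p = 0.0101), and Cx3cr1 (ENSMUSG00000052336, chr9:119901616-120069879), a chemokine receptor of circulating effectors, from 31.8 ± 18.3 to 1.76 ± 0.51 CPM (-3.92 ± 0.53, adjusted p = 0.00787). Itgb1 fell from 777 ± 41.3 to 65.9 ± 9.17 CPM (-3.30 ± 0.36, adjusted p = 0.00484). Ly6c2 gave adjusted p = 0.0539 (0.0378 with a block) and Il22 measured 14.9 ± 19.1 and 1194 ± 873 CPM (adjusted p = 0.0778, and 0.00825 with a block, within 4.8e-05 to 0.264). S1pr1 gave -1.01 (adjusted p = 0.0616, and 0.0409 with a block, within 0.0132 to 0.219).

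In KO recipients edgeR called 1065 genes, 738 higher and 327 lower in colon, and 2516 (1457 higher, 1059 lower) with a block. Of the calls 69.3% were higher, against 57.9% with the block and 43.6% by limma. The count was 680 without spleen control 1, 653 without spleen control 2, 241 without spleen KO 1, 209 without spleen KO 2, 214 without colon KO 1 and 398 without colon KO 2. Areg, Ctla4, Nr4a2 and Itgb1 passed without any single library. Calls ended for Ifng without spleen KO 1 (0.0817), colon KO 1 (0.0653) or colon KO 2 (0.0705), for Gzmb without spleen KO 1 (0.0528), for S1pr5 without colon KO 1 (0.0879) or KO 2 (0.0654), and for Cx3cr1 without colon KO 1 (0.0873) or KO 2 (0.0538). The Il17a call ended without spleen KO 1 (0.0725), spleen KO 2 (0.111), colon KO 1 (0.112) or colon KO 2 (0.0599), and without the filter (0.0617).

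The tissue calls were shared between genotypes. Genes higher in colon in both numbered 453 (32.0 expected of independent lists) and genes lower in both 122 (4.64 expected), and 0 genes were called in opposite directions. Across 11636 genes, which are not independent replicates, the log2 fold changes had r = 0.868 and rho = 0.822. The 2 comparisons share no library but hold the same tissues and batches and share an estimate of the spread, so their calls are not independent. The interaction, which tests the same difference, called 0 genes as given above. It recovered 1% of simulated 2-fold and 15% of 4-fold changes, so its 0 calls do not show equal tissue differences. In KO recipients 15 lists passed. TCR activation genes had 11 higher and 1 lower of 19 (11 and 1 over the list alone; median 2.45, adjusted p = 9.2e-14, and 0.168 with an estimated correlation), STAT3 target genes 8 higher and 1 lower of 18 (10 and 1; adjusted p = 1.4e-08, and 0.120 with an estimated correlation), with Socs3 at 2.53 and Pim1 at 3.21, and Th17 genes 5 higher of 19 (10; adjusted p = 8.9e-06, and 0.303 with an estimated correlation). Tissue residency genes had 6 higher and 2 lower of 22 (15 and 2; adjusted p = 2.2e-06, and 0.168 with an estimated correlation) and Th1 genes 4 higher of 20 (7 and 1 lower; adjusted p = 0.0138, and 0.396 with an estimated correlation). Naive genes had 4 lower of 18 (2 higher and 7 lower over the list alone; adjusted p = 0.00167, 0.294 with an estimated correlation, and 0.129 without colon KO 2). Heat shock genes had 7 higher of 24 (13; adjusted p = 6.9e-11, and 0.303 with an estimated correlation), and proliferation genes fell as a list with 2 of 32 higher (adjusted p = 8.9e-06, and 0.582 with an estimated correlation), Ccnb2 among them by 2.73 (1 called over all genes and 0 over the list alone). The Ccnb2 call ended without any single spleen or colon KO library (adjusted p = 0.0707 to 0.233) and without the filter (0.129), and the proliferation call ended without spleen KO 2 (0.0518). The lowest adjusted p over 17 alternatives was 5.5e-18 for TCR activation, 2.0e-10 for STAT3 target, 5.8e-12 for Th17, 2.6e-10 for residency, 0.00407 for Th1, 2.1e-05 for naive, 2.9e-14 for heat shock and 9.2e-14 for proliferation genes, and the highest was that with an estimated correlation.

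Other lists in KO recipients passed beside these. Markers of other cells were higher in colon for stroma (7 higher of 11, 9 over the list alone; median 5.68, adjusted p = 2.6e-12, and 0.168 with an estimated correlation) and epithelium (1 higher of 14, 1 over the list alone; 5.32, adjusted p = 0.00302, and 0.582 with an estimated correlation), and lower for mast cells and basophils (1 lower of 4, 1 over the list alone; -3.12, adjusted p = 0.0138, and 0.306 with an estimated correlation). The epithelial call ended in the CD3-high clusters (2.35, 0.609) and without colon KO 2 (1.38, 0.238), and the stromal median was 8.63 without spleen KO 2 and 4.41 in the CD3-high clusters (0.0102). The mast cell call ended without spleen KO 1, where the median turned to 1.45 (0.211), colon KO 1 (-0.88, 0.953), spleen KO 2 (-1.65, 0.0509) or colon control 2 (-1.65, 0.0506), and the median was -1.68 without spleen control 1, -1.65 without spleen control 2 and -6.01 without colon KO 2. Apoptosis and survival genes had 11 higher and 2 lower of 22 (12 and 2 over the list alone; adjusted p = 7.3e-09, and 0.168 with an estimated correlation) and Treg genes 4 higher of 13 (5 and 1 lower over the list alone; adjusted p = 5.7e-05, and 0.168 with an estimated correlation). Interferon-stimulated genes had 2 lower of 30 (0 over the list alone; -0.38, adjusted p = 0.0442, and 0.655 with an estimated correlation), and ribosomal protein genes 37 of 37 on the higher side with no member past the threshold (0.38, adjusted p = 0.0442, and 0.757 with an estimated correlation). The interferon call ended without colon control 1 (0.0577), spleen KO 2 (-0.24, 0.128), colon control 2 (0.0576) or colon KO 2 (0.117), with a median of -0.66 without colon KO 1. The ribosomal call ended without colon control 1 (0.0503), colon KO 1 (0.09, 0.953), spleen KO 2 (0.117) or colon control 2 (0.0561), in the CD3-high clusters (0.0599) and with proliferating cells left out (0.127), and the median was 0.70 without colon KO 2.

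**Figure D2:**
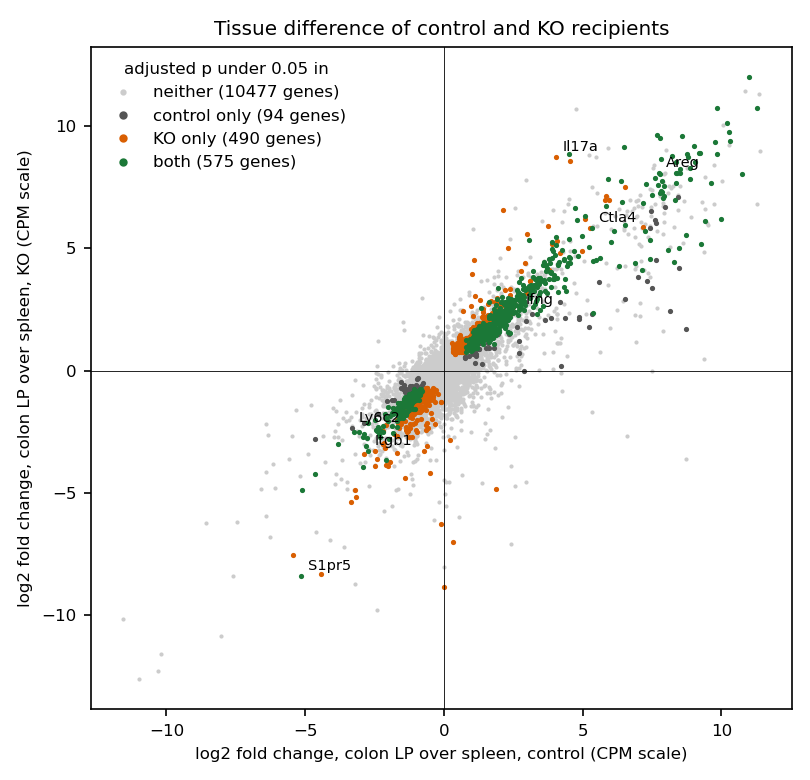
Log2 fold change of colon lamina propria over spleen in control (horizontal) against KO recipients (vertical), each point a gene. Of these 575 genes were called in both, 94 in control only, 490 in KO only and 10477 in neither, with 7 genes labelled.

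The comparison of KO with control over all 4 tissues asked for an average effect of the receptor. Il22 gave 2.04 ± 0.82 (0.50 in the CD3-high clusters), Il10 1.34 ± 0.46, Gzma -1.21 ± 0.42, Cd160, an NK and T cell receptor, -0.99 ± 0.43, S1pr1 -0.57 ± 0.19, Il7r -0.45 ± 0.17 and Ifng 0.12 ± 0.24, none past the threshold (n = 6 libraries per genotype). These 6 libraries came from 2 batches, and the fit without a block took them as independent. In batch 1 alone Gzma gave 0.16, Cd160 0.47, S1pr1 0.04 and Il7r -0.15, against -1.85, -1.50, -0.89 and -0.62 in batch 2 alone, so batch 1 did not share the lower values of Gzma, Cd160 and S1pr1. The smallest p-values on the higher side belonged to Mcpt8 (6.83 ± 0.85, adjusted p = 0.405), Prss34, the mucus protein gene Fcgbp (5.08), Phlda1 (0.95 ± 0.19), a gene induced by T cell activation, and Tox2 (0.56 ± 0.13). On the lower side were Ehd3 (-0.59 ± 0.13), Ankrd35 (-1.60 ± 0.36), Rgs10 (-0.44 ± 0.10), Lcn4 (-0.96) and Gramd3 (-0.57 ± 0.14). By edgeR 0 of 12044 genes passed (573 at an unadjusted p under 0.05), by limma 0, and by DESeq2 2, Apoa1 and Phlda1 (Phlda1 within adjusted p = 0.0174 to 1 over 25 alternatives), which were named after their calls were seen. Phlda1 measured 101 and 173 CPM in colon control and KO. Batch 1 alone called 9 genes, Apoe, C1qa, C1qb, C1qc, Ccl17, Dcn, Gjb2, Hes1 and Myl9 (4 higher and 5 lower), and batch 2 alone called 0 (1595 at an unadjusted p under 0.05). Without either epithelial library the lipoprotein gene Apoa4 was called (adjusted p = 0.0186 without control and 0.0177 without KO).

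Among lists over all tissues 9 passed. Heat shock genes rose in KO (23 of 24 higher, median 0.60, adjusted p = 3.2e-13, and 0.371 with an estimated correlation), with Hspa1b at 2.76 ± 1.11 and Dusp1 at 0.69 ± 0.24. Ribosomal protein genes fell (0 of 37 higher, -0.21, adjusted p = 2.6e-12, and 0.556 with an estimated correlation) and interferon-stimulated genes rose (27 of 30 higher, 0.34, adjusted p = 3.3e-11, and 0.371 with an estimated correlation), with Iigp1 at 0.97 ± 0.37. Co-inhibitory receptor genes rose (11 of 14 higher, 0.10, adjusted p = 0.00472, and 0.371 with an estimated correlation), and 3 members were higher when adjusted over the list alone, against 0 over all genes, with Tox at 1.13 ± 0.26. Th17 genes rose (17 of 20 higher, 0.43, adjusted p = 0.00368, and 0.560 with an estimated correlation), but in the CD3-high clusters the median was 0.13 (adjusted p = 0.284). Proliferation genes fell (2 of 32 higher, -0.27, adjusted p = 0.000636, and 0.677 with an estimated correlation). Naive and central memory genes fell (7 of 18 higher, -0.15, adjusted p = 0.0234, and 0.560 with an estimated correlation), but not in the CD3-high clusters (0.147) or in batch 1 alone (0.390). Dendritic cell markers rose too (median 0.78, but 1.5 without spleen control 1, 1.25 without colon control 1, 0.44 without small intestinal control, 0.45 without small intestinal KO and 0.11 in batch 1 alone; adjusted p = 0.000439, and 0.556 with an estimated correlation), with adjusted p = 0.101 in the CD3-high clusters and 9.7e-12 to 0.998 over 24 alternatives. Mast cell and basophil markers rose (5 of 5 higher, 3.17, adjusted p = 0.000439, and 0.371 with an estimated correlation), but not without spleen KO 1 (0.0919) or spleen KO 2 (0.145), and the median was 6.36 without colon control 1, 2.08 without epithelial control and 2.10 without epithelial KO. In batch 1 alone the interferon list gave 0.01 (adjusted p = 0.998) and the ribosomal list -0.07 (0.0702), and in batch 2 alone the co-inhibitory list gave 0.11 (0.190).

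Leaving out single libraries, without a block, again moved the lists over all tissues. Heat shock genes gave 0.39 without either small intestinal library. The co-inhibitory call ended without spleen KO 2 (0.15, adjusted p = 0.0567), and its median was 0.21 without colon control 1, 0.04 without colon KO 1, 0.02 without colon control 2, 0.19 without colon KO 2 and 0.20 without either epithelial library. The Th17 call ended without spleen KO 1 (0.20, 0.150), small intestinal control (0.23, 0.178) or small intestinal KO (0.21, 0.162), and the median was 0.28 without spleen control 2. The proliferation call ended without spleen KO 1 (-0.18, 0.0520), colon control 2 (-0.03, 0.189), small intestinal control (-0.05, 0.487) or small intestinal KO (-0.06, 0.505), with the proliferating cells left out (0.10, 0.220) and in spleen and colon alone (0.05, 0.336), and the median was -0.16 without colon KO 1 and -0.57 without spleen KO 2. The naive call ended without spleen control 1 (0.0810), spleen control 2 (-0.05, 0.0550), spleen KO 2 (-0.10, 0.145), colon control 1 (-0.07, 0.0890), colon KO 2 (-0.04, 0.234), epithelial control (0.0778) or epithelial KO (0.0709), and its median was -0.10 without spleen KO 1, -0.29 without colon KO 1, -0.24 without small intestinal control and -0.25 without small intestinal KO. Over 24 alternatives the adjusted p ran from 9.5e-08 to 0.560 for naive, 8.9e-21 to 0.371 for heat shock, 2.4e-23 to 0.556 for ribosomal, 1.2e-16 to 0.998 for interferon-stimulated, 3.1e-07 to 0.371 for co-inhibitory, 6.7e-19 to 0.560 for Th17 and 4.9e-12 to 0.677 for proliferation genes.

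Small intestinal lamina propria had 1 library per genotype, so values there carry intervals for counting error only and no test. Il22 measured 347 CPM (95% interval 333 to 362) in control and 5140 CPM (5060 to 5220) in KO, a log2 ratio of 3.89 (3.82 to 3.95), and 0.63 (0.51 to 0.75) in the CD3-high clusters. Ifng measured 156 (146 to 165) and 260 (242 to 279) CPM, a ratio of 0.74 (0.61 to 0.88), and Il17a 46.9 (41.8 to 52.5) and 72.7 (63.6 to 82.9) CPM, a ratio of 0.63 (0.38 to 0.89). Gzma measured 3298 (3254 to 3342) and 509 (485 to 535) CPM, a ratio of -2.70 (-2.77 to -2.62), and stayed at -2.34 in the CD3-high clusters, while Gzmb measured 828 and 816 CPM. Cd160 measured 283 (270 to 296) and 75.3 (66.0 to 85.6) CPM, and Itgae, the integrin of intraepithelial cells, 152 (143 to 162) and 32.2 (26.2 to 39.1) CPM.

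The largest ratios on the higher side in small intestine were those of Pxdc1 (5.04), Fcer1g, an Fc receptor adaptor (4.97), Cd83 (4.85), Atf3 (4.83) and Sdc4 (4.57), and in the CD3-high clusters these were 1.41, 3.87, 0.90, 2.94 and 0.42. On the lower side were Reg3b (-3.76), Gzma, the cell cycle gene Stmn1 (-2.26), Itgae (-2.24) and S100a4 (-2.04). Heat shock genes had a median of 1.65 with 24 of 24 higher (percentile 100 of random matched lists), interferon-stimulated genes 0.52 with 20 of 22 higher (100), proliferation genes -1.41 with 0 of 32 higher (0), and cytotoxic genes -0.49 with 6 of 20 higher (0). Naive and central memory genes had a median of 0.59 with 12 of 16 higher (100), and 0.76 in the CD3-high clusters, against pair medians of 0.04 and -0.52 in colon lamina propria and -0.05 and -0.41 in spleen (batch 1 and batch 2), and Th1 genes 0.18 with 11 of 20 higher (99.7). Signs of cell quality moved with these values: mitochondrially encoded genes had a median of 0.56 with 11 of 13 higher (percentile 99.99), 7.72% of KO against 1.73% of control cells had over 10% mitochondrial UMIs, and median depth was 1863 against 2553.5 UMIs per cell. Th17 genes had a median of 1.54 with 15 of 17 higher in all cells (percentile 100) and -0.03 in the CD3-high clusters. Markers of cell types moved as well: the dendritic cell list had a median of 2.96 with 7 of 7 higher (100) and 0.54 in the CD3-high clusters, the epithelial list -2.50 with 1 of 16 higher (0) and 0, and the T cell list -0.48 with 1 of 7 higher (1.89) and -0.01. Over 5680 genes with at least 50 UMIs in each library the median absolute log2 ratio was 0.263.

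Colon epithelium also had 1 library per genotype. Ifng measured 520 CPM (507 to 533) in control and 313 CPM (302 to 324) in KO, a log2 ratio of -0.73 (-0.80 to -0.67). Gzma measured 4574 (4536 to 4613) and 3290 (3255 to 3326) CPM, Gzmb 700 (685 to 715) and 726 (710 to 743) CPM, and Cd160 391 (380 to 403) and 227 (217 to 236) CPM, a ratio of -0.79 (-0.86 to -0.72). The chemokine genes Xcl1 (-1.94), Ccl3 (-1.88) and Ccl4 (-1.72), with Esm1 (-1.74) and the enkephalin gene Penk (-1.71), had the largest ratios on the lower side. On the higher side were Mptx1 (7.98), Reg3b (6.31), Reg3g (5.97) and the goblet cell gene Clca1 (5.85), with Hspa1a (ENSMUSG00000091971, chr17:34969190-34972156), an inducible chaperone, at 6.08 (5.93 to 6.24). Mptx1 and Reg3b gave 4.41 and 3.08 in the CD3-high clusters, and Hspa1a 6.14. Th1 genes had a median of -0.30 with 5 of 20 higher (percentile 0), STAT3 target genes -0.34 with 3 of 15 higher (0), proliferation genes -0.32 with 2 of 32 higher (0), heat shock genes 0.62 with 21 of 24 higher (100) and interferon-stimulated genes 0.29 with 18 of 22 higher (100). In small intestine the STAT3 target genes went the other way, with a median of 0.28, 9 of 15 higher (99.57), and 0.05 in the CD3-high clusters. Epithelial markers had a median of 4.10 with 16 of 16 higher, and 1.57 in the CD3-high clusters, and mitochondrially encoded genes 0.37 with 13 of 13 higher, and -0.04 in the CD3-high clusters. Over 8317 genes the median absolute log2 ratio was 0.188.

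Cell clusters asked whether the mix of cells differed with genotype. Cluster 5, led by S1pr5, Cx3cr1, Klrg1 and Zeb2, genes of circulating effector cells, made up 17.2% (95% interval 14.9 to 19.7) of spleen KO against 3.59% (2.68 to 4.71) of spleen control cells in batch 1, and 4.99% (4.31 to 5.73) against 1.54% (1.19 to 1.97) in batch 2 (log2 2.11 ± 2.36, adjusted p = 0.988). Cluster 3, led by Eomes, Gzmk, Esm1 and Il10, made up 12.3% and 3.74% of colon KO against 4.33% and 2.35% of colon control cells (1.26 ± 2.30), 7.53% against 3.42% in small intestine and 1.48% against 0.350% in epithelium, but 2.75% against 7.12% and 8.67% against 4.61% in spleen. Cluster 12, with high Il22 and Pxdc1 and low CD3, made up 27.9% (25.7 to 30.2) of small intestinal KO against 0.756% of control cells, and 5.93% (5.11 to 6.83) and 1.86% (1.44 to 2.35) of colon KO against 3.66% (2.77 to 4.74) and 0.209% (0.0839 to 0.429) of colon control cells (1.01 ± 2.29, adjusted p = 0.973). Cluster 2, led by Ccl1, Ccl3, Ccl4, Xcl1 and Ifng, made up 3.74% of epithelial KO against 8.84% of control cells. The proliferating cluster 9 made up 0.872% of small intestinal KO against 5.56% of control cells, and 7.54% and 19.9% of spleen KO against 9.71% and 8.11% of spleen control cells. By edgeR 0 of 8 clusters tested in colon and 0 of 9 in spleen passed (smallest adjusted p = 0.973 and 0.988, and 0.903 and 0.923 with a block). Clustering had no batch integration, and some clusters split by batch. Cluster 8 held 84.2% and 0.298% of colon control cells in batch 1 and batch 2. Standard errors without a block were 2.26 to 2.36 on the log2 scale. The test therefore had little power, and its 0 calls do not show equal shares. Leaving out single libraries, which also unbalanced the batches, moved these log2 values. Cluster 12 in colon gave -0.05 without colon KO 1 and 4.19 without colon control 1, and cluster 3 gave 0.16 without colon KO 1 and 1.88 without colon KO 2. Cluster 5 in spleen gave 0.96 without spleen KO 1 and 2.84 without spleen control 1.

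**Figure D3:**
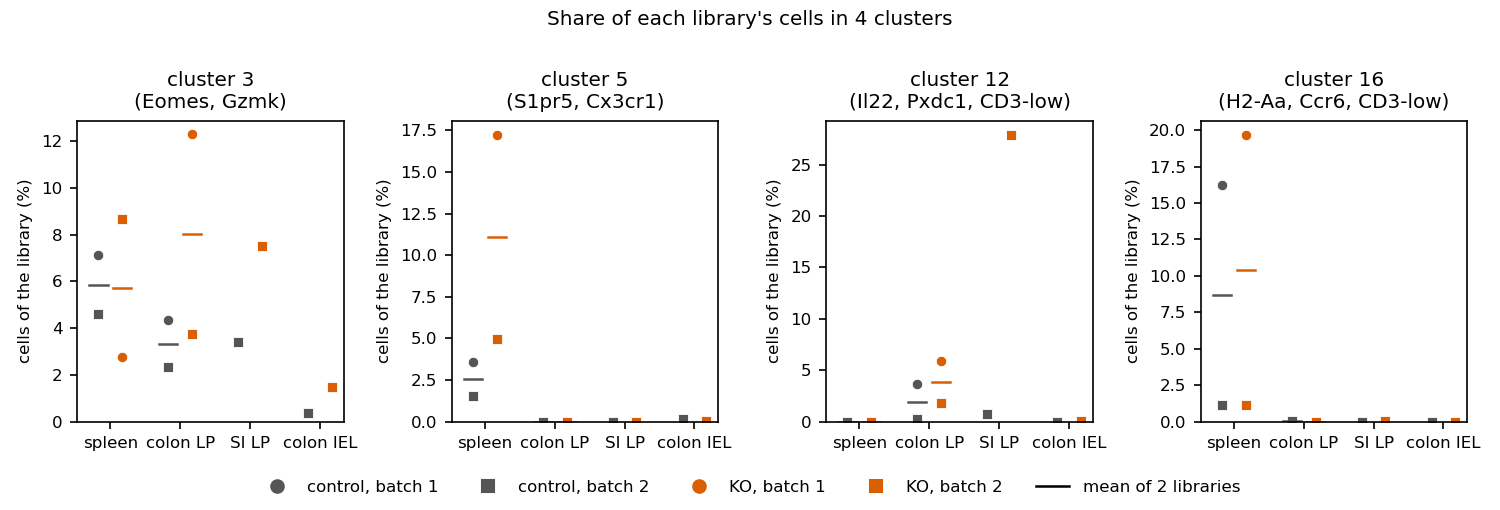
Share of each library's cells (percent) in clusters 3, 5, 12 and 16, by tissue. Circles are batch 1, squares batch 2, grey control and orange KO, and lines are means of 2 libraries.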

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

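Tests chosen only after the result was seen were those of handling and of CD3-low cells for the heat shock list and that of NK cells for cluster 5, and the single-batch fits and the mitochondrial limit were also added then. Of 55 results tested over the 6 pairs of KO and control libraries, 5 had a single pair far from the others, and chance gives about 1 in 20. These gene and list ratios had 1 CPM added, which weighs on genes of low counts. The log2 ratio of Il23r was 2.995 in small intestine against -0.302 to 0.84 in the other pairs. Without the added CPM Il23r gave 3.324 in small intestine and -1.009 in colon epithelium (7 and 3 UMIs). The search for far pairs was not run on such ratios, so the Il23r flag may rest on the added CPM. Fcgbp, a mucus gene of goblet cells, had 5.036 in colon epithelium against 0 in the others. Tox2 had 0.178 in colon lamina propria of batch 2 against 0.547 to 0.721. Stromal markers had a median of 0.872 in colon lamina propria of batch 1 against -0.415 to 0.013, and erythroid markers 9.505 in spleen of batch 2 against -1.314 to 1.005.

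Lists passed by the interaction, the KO effect in colon lamina propria minus that in spleen, at the preset correlation (adjusted p = 6.6e-06 to 0.00719), and none did with an estimated correlation (0.928 for each). The list medians were -0.688 for proliferation, -0.422 for interferon-stimulated, 0.268 for heat shock and 0.259 for ribosomal protein genes. For markers of other cells they were -0.791 for macrophages, -5.442 for mast cells and basophils, and -4.142 for erythroid cells. The macrophage call ended without colon control 1, where the median turned to 0.458 (adjusted p = 0.650), colon KO 1 (0.226), spleen control 2 (-0.207, 0.306) or spleen KO 2 (-0.498, 0.0982), and the median was -1.995 without spleen control 1, -1.746 without colon control 2, -1.333 without colon KO 2 and 0.038 in the CD3-high clusters (0.476). The mast cell call ended without spleen control 1 (0.126), spleen KO 1 (0.124), colon control 1 (0.182) or colon KO 1 (-2.754, 0.817), and the median was -8.461 without colon KO 2. The erythroid call ended without colon control 1, where the median turned to 7.429 (0.504), spleen control 2 (0.306), spleen KO 2 (0.109) or colon KO 2 (0.510), and the median was -11.323 without spleen control 1, -12.347 without colon KO 1 and -9.374 with a block.

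The Il22 and Il23r values of the small intestinal KO library went with cluster 12, which held 27.9% of its cells. With CD3-low clusters left out, the Il22 ratio was 0.628 against 3.887 over all cells, which argues for cells of cluster 12 as the source of most of the difference. Of the Il22 UMIs, 5.596 lay in CD3-high cells per 100 in cluster 12, within the 0.812 to 57.5 of the other leading genes of cluster 12, so free RNA from those cells may account for part of what was left. Cluster 12 also made up more of colon lamina propria KO than of control cells in both batches (5.93% against 3.66%, and 1.86% against 0.209%). The test of shares, which had little power, did not call it. Whether the receptor, the animal or the dissection brought more of these cells stays open.

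Heat shock genes were higher in colon lamina propria KO. The batch 1 pair had a median of 0.034 against 1.168 in the batch 2 pair, so handling of single libraries in batch 2 may explain the colon result. Cell quality moved with the batch 2 pair, where 1.72% of KO against 0.477% of control cells had over 10% mitochondrial UMIs and median depth was 2250 against 2884 UMIs, but without such mitochondrial cells the list had a median of 0.513 in both batches together, as with them. CD3-low cells are argued against, since without them the batch 2 pair had 1.303, and other pairs did not follow batch alone: batch 2 had 1.649 in small intestine, 0.624 in colon epithelium and -0.080 in spleen, and batch 1 had 0.391 in spleen (20 of 24 higher). A response of the cells to the loss of the receptor was not tested and stays open beside handling.

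Cluster 5 took a larger share of both spleen KO libraries, and the test of shares, which had little power, did not call it. Cd3e in cluster 5 was 107.18% of that in the other CD3-high clusters, so the cluster as a whole carried Cd3e. Cluster 5 was in that set because of its T cell markers, which largely fixed this outcome. A mean also cannot exclude a minority of NK cells lacking CD3. With cells thinned to 1000 UMIs, cells with at least 2 UMIs of S1pr5, Cx3cr1, Klrg1, Klre1 and Zeb2 made up 9.68% (7.91 to 11.7) against 3.09% (2.25 to 4.14) in batch 1 and 4.67% (4.02 to 5.39) against 1.42% (1.07 to 1.83) in batch 2. The lower of the fold differences was 3.1327, which argues against deeper cells in KO as the cause. More circulating effector cells in spleen without the receptor is a hypothesis that 2 libraries per group leave open.

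Over all tissues 573 genes had an unadjusted p under 0.05 between KO and control without a block. With each pair of tissue and replicate number as a block there were 1040. The splits were fitted without a block, so they leave batch out. Of 68 splits of the 12 libraries drawn from 462, 20 gave as many genes, the real split included, the highest other with 3121, so chance is not excluded. That highest split puts all 4 batch 1 libraries on the same side and calls 535 genes. The other drawn splits that do so gave 1314, 2348 and 1401 genes and called 5, 0 and 2. Batch does structure the samples: over the spleen and colon lamina propria libraries the second principal component (21.0%) parted the batches. The real split puts 2 batch 1 libraries on each side. Batch 1 alone called 9 genes and batch 2 alone 0 (edgeR, 1595 at an unadjusted p under 0.05). Of the 32 splits that part every pair, as the real split does, 4 gave as many genes, the real split included, and the highest other, which mixes the genotypes on each side, gave 911.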

How the results depend on the processing

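The fit with CD3-high clusters and a block, the limit on mitochondrial UMIs and the single-batch fits were chosen only after results were seen. Over all alternatives named genes kept direction and side of the threshold in 14436 values, passed newly in 195 and no longer passed in 347. Lists did so in 2723, 147 and 205 values, with 2 reversed. Cluster shares called 0 clusters by edgeR in all 153 values. The cause of each change below was not tested unless stated. Fits that left out a spleen or colon lamina propria library had no block and so also unbalanced the batches.

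The interaction called 0 genes and colon lamina propria 0 genes by edgeR without any single library. With a block, colon called 1 gene, spleen 1, and the tissues 1717 (control) and 2516 (KO), and in the CD3-high clusters 0 in colon and 0 in spleen (edgeR, 203 and 262 at an unadjusted p under 0.05) and 1787 and 2726 between tissues. The block alone let 36 values of named genes and 9 of lists pass newly, ended the calls of 1 gene (Dcn) and 1 list (Th1 genes in spleen), and changed no other call. Without the filter spleen called 1, the control tissues 1167 and all tissues 3, DESeq2 called 2 in spleen, 1222 and 1679 between tissues and 2 over all tissues, limma 2 in spleen, and equal depth 1 over all tissues. Batch 1 alone called 9 over all tissues. Without each library in turn the counts were 0 to 1 in spleen, 10 to 945 and 209 to 1399 between tissues in control and KO, and 0 to 1 over all tissues; fewer libraries leave fewer residual degrees of freedom.

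Lists past the threshold numbered 7 in colon, 11 in spleen, 7 for the interaction, 13 and 15 between tissues and 9 over all tissues. With an estimated correlation each became 0. Colon had 2 in CD3-high clusters and 3 with a block as well, and spleen 7 without the filter and 7 at equal depth. Without each library in turn they were 7 to 13 in colon (13 without control 1), 9 to 13 in spleen, 3 to 8 for the interaction (3 without colon KO 1 or spleen KO 2), 12 to 15 and 12 to 19 between tissues, and 6 to 12 over all tissues. Proliferation genes reversed in spleen without KO 2 (-0.43, and up to 0.851 without KO 1) and in the interaction without colon control 2 (0.349, and down to -1.349 without colon control 1).

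In small intestine the median absolute log2 ratio of 0.263 moved to 0.241 in CD3-high clusters and 0.25 at equal depth, and in colon epithelium 0.188 moved to 0.171 in CD3-high clusters and was 0.184 at equal depth. Depth limits what can be said of rare transcripts: Il23r had 22 and 106 UMIs in small intestine and 7 and 3 in colon epithelium, and edgeR recovered at most 6% of simulated 2-fold changes in comparisons of 2 libraries per group.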

Other observations

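The test of innate markers reported here was chosen only after the result was seen. Clusters 12 and 16 were among those chosen for low T cell markers. Cluster 12 measured 22812 CPM of Il22, 83.8 CPM of Il23r and 222 CPM of the stem cell factor receptor gene Kit, with Cd3e at 27.8 CPM against 767 CPM outside the cluster. Cluster 16 measured 75.4 CPM of Il23r and 530 CPM of Ccr6, a chemokine receptor of lymphoid tissue inducer cells, with Cd3e at 46.5 CPM. Genes of antigen presentation, which the dendritic cell list holds, were high in both, with H2-Aa at 1567 and 3424 CPM and Cd74 at 7683 and 10337 CPM in clusters 12 and 16. Cluster 16 made up 16.2% and 19.7% of spleen control and KO cells in batch 1, and 1.13% and 1.11% in batch 2.

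A hypothesis is that clusters 12 and 16 may hold lymphoid tissue inducer or other group 3 innate lymphoid cells. Of 12 such markers, Il23r among them, 8 were at least 2-fold higher in both clusters than in all other cells, 9 in cluster 12 and 10 in cluster 16. The most abundant markers were Tmem176a (1964 and 2478 CPM in clusters 12 and 16), Id2 (1316 and 2240 CPM) and Ltb (1064 and 2279 CPM), and all 12 were also counted in the other cells, Id2 at 1190 and Il7r at 275 CPM outside cluster 12. Of the dendritic cell markers, 6 were at least 2-fold higher in each cluster, against 3 and 4 of the NK and ILC markers in clusters 12 and 16. The 10 leading genes of cluster 16 held 3 dendritic cell markers (H2-Aa, H2-Eb1, H2-Ab1) and 0 of the NK and ILC list, but also Ccr6 of the 12 innate markers. Those of cluster 12 held 0 of either list. Cells of a dendritic kind, or a mixture, therefore stay open for both clusters. No sort or gate is given in the sources used here. Some cells of this kind carry CD4, and a gate on CD3 would remove them.

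Main clusters followed tissue and batch. Cluster 0 (Itgae, Cd160) made up 81.6% and 72.0% of colon epithelial KO and control cells, cluster 7 (Areg, Tnfaip3, Pim1) 83.9% and 81.1% of colon lamina propria cells in batch 2, and cluster 8 (Ramp3, Crem, Xist) 72.7% and 84.2% of those in batch 1. In the same order of KO and control, cluster 11 made up 47.9% and 54.0% of spleen cells in batch 1, and clusters 1 (Igfbp4, Id3) and 4 (Itgb1, Ly6c2) took most of spleen cells in batch 2. Cluster 6, led by Hspa1a and Hspa1b, had a median of 672 UMIs per cell and 9.18% mitochondrial UMIs, and made up 13.5% of small intestinal KO cells against 0.40% of control cells.

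Hspa1a was higher in KO than in control in each batch 2 pair, at 4437 and 47.4 CPM in colon lamina propria, 2914 and 183 CPM in small intestine, 1955 and 28.8 CPM in colon epithelium, and 68.9 and 1.87 CPM in spleen. It was higher in KO in both batch 1 pairs too, at 1107 and 924 CPM in colon and 373 and 109 CPM in spleen.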
